A study of Rattus norvegicus with 8 samples.

How the data were processed

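Small RNA sequencing was done on exosomes of rat nucleus pulposus cells and nucleus pulposus progenitor cells, with 4 libraries of each. Per the labels' protocols, RNA was isolated with an exosome RNA kit and libraries were made with an Illumina TruSeq small RNA kit. CASAVA 1.8 is named in the submitters' processing notes. The aligner, the miRBase version and the genome build are not given in the sources used here.

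The authors deposited estimated counts per miRNA row. Of 5804 values above 0, 82.3% were whole within 1e-09, and 284 of 1512 rows shared their sequence with another. Such rows, and near-identical miRNAs such as those of the let-7 family, are uncertain in how reads were split. Values above 0 and under 5 occurred 402 times, the smallest being 1.25. The scaled signal columns that the authors deposited equalled the count times 1 factor per library, with a spread of at most 0.00244% over values above 500. Library totals ranged from 329011 to 1416940 counts, which limits the precision of low rows.

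Estimated counts were rounded to whole numbers. Groups and replicate numbers came from the sample titles. The comparison used edgeR 4.0.16 in R 4.3.3 with TMM factors, filterByExpr, the two-sided quasi-likelihood test with group as the only term, and Benjamini-Hochberg adjustment over 464 rows (414 sequences). Of these rows 298 carried rat names, 129 names of other species and 37 were predicted candidates. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 and with an estimated one, adjusted by Benjamini-Hochberg over lists with at least 3 tested members. Library measures were compared by two-sided exact permutation tests over 70 arrangements with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. Thinned numbers of rows are means of 20 thinnings. Figures were drawn with matplotlib 3.10.9.

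The tests were tested on simulated data. In 1 draw with 200 changed rows, edgeR on all 8 libraries recovered 20% of rows changed 2-fold and 59% of rows changed 4-fold over 435 rows, with 2 unchanged rows called. Simulated without NPC replicate 1 it recovered 39% and 70% over 489 rows, with 2 unchanged rows called. Rows were drawn independently, without a trend shared by the rows of a library. With so many changed rows the Benjamini-Hochberg adjustment is more lenient than with few, so these percentages may be too high for the deposited data.

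The tests, the lists and the naming rule were fixed before the data were examined, with these exceptions. A list member was matched by name to 1 row, rat names and the highest count first. After the table had been seen, rows without a base substitution were put first, and after list results had been seen, members with an identical sequence were counted once. The naming rule took rows with an adjusted p under 0.05 whose groups did not overlap (0 rows), the 5 rows with the highest mean CPM, and up to 4 members of each list by mean CPM. The number of members was set at 2 after values had been seen, by abundance alone, and members that passed adjusted over their list alone were added.

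Alternatives fixed beforehand were DESeq2 size factors, total count scaling, upper-quartile factors, no filter, a filter of 10 CPM in at least 4 libraries, the Wald test of DESeq2 1.42.0, limma-voom, a replicate block, sums per mature name, rat names only and each library left out. For lists they were DESeq2 size factors, total count scaling, the block, the estimated correlation and each library left out. Added after the data were seen were the authors' scaling, sums per sequence, a GC correction (a loess curve of each library on GC percent with a span of 0.75, as an offset), the same without NPC replicate 1, neither library numbered 1, thinned libraries, and for lists the remaining alternatives of the row test. For the row and list tests libraries were thinned in a single draw, with counts under 5 then set to 0. Hairpin coordinates are those of the deposited table.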

Results

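Small RNA was sequenced from exosomes, the small membrane vesicles that cells release, of 2 kinds of rat intervertebral disc cell. There were 4 libraries from exosomes of nucleus pulposus cells (NPC), the cells of the gelatinous core of the disc, and 4 from exosomes of nucleus pulposus progenitor cells (NPPC). The deposited table gave an estimated count for each of 1512 miRNA rows, of which 455 carried rat miRBase names, 406 carried names of other species and 651 were predicted candidates. The NPC libraries held 329011, 618196, 681591 and 537520 counts for replicates 1 to 4, and the NPPC libraries held 819845, 1090492, 1416940 and 1310818. Every NPPC library was deeper than every NPC library, with means of 541580 ± 153487 (SD, n = 4) in NPC and 1159520 ± 264134 (SD, n = 4) in NPPC libraries. The two-sided exact permutation p was 0.0286, the smallest that 70 arrangements can give. The labels did not say whether the libraries of a group came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

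By group mean the most abundant miRNA in the exosomes of both cell types was miR-21-5p, which is common in mesenchymal cells, with 21.3% ± 10.9 (SD, n = 4) of NPC counts and 29.7% ± 1.42 (SD, n = 4) of NPPC counts. NPC replicate 1 held 5.55%, the other NPC libraries 24.2% to 30.5%. Both arms of miR-199a, another mesenchymal miRNA, came next. miR-199a-5p took 7.76% ± 2.89 (SD, n = 4) in NPC and 5.84% ± 0.307 (SD, n = 4) in NPPC exosomes, and miR-199a-3p took 6.71% ± 1.32 (SD, n = 4) and 6.68% ± 0.482 (SD, n = 4). miR-27b-3p took 6.47% ± 1.10 (SD, n = 4) and 5.37% ± 0.125 (SD, n = 4), and miR-143-3p, known from smooth muscle, took 5.44% ± 0.372 (SD, n = 4) and 4.20% ± 0.455 (SD, n = 4). None of these 5 passed the edgeR quasi-likelihood test, where Benjamini-Hochberg adjusted p lay between 0.640 and 0.914. Their log2 fold changes of NPPC over NPC were 0.60, -0.021, 0.21, 0.056 and -0.096 in this order, and that of miR-21-5p was 0.25 without NPC replicate 1. With total count scaling those of miR-199a-3p and miR-27b-3p turned to -0.0085 and -0.27. Each library's own 10 most abundant rows held 58.1% ± 5.16 (SD, n = 4) of NPC and 61.1% ± 0.386 (SD, n = 4) of NPPC counts, with a two-sided exact permutation p of 0.314. With a library left out the difference ran from 0.450 percentage points without NPC replicate 1 to 4.36 without NPC replicate 3, the latter with an exact permutation p of 0.0286.

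The series compared the miRNAs of NPPC exosomes with those of NPC exosomes. The row with the smallest p was miR-146a-5p, an inducible miRNA that restrains NF-kappaB signalling by repressing TRAF6 and IRAK1. It stood at 85.3 ± 43.8 CPM (SD, n = 4) in NPC and 939 ± 221 CPM (SD, n = 4) in NPPC exosomes, a log2 fold change of 3.46 ± 0.51 (SE), and all 4 NPPC libraries lay above all 4 NPC libraries. Its adjusted p over all rows was 0.0575 by edgeR's two-sided quasi-likelihood test with Benjamini-Hochberg adjustment, so it did not pass. The deposited table places its hairpin on chromosome 10 from 28962476 to 28962570, minus strand, in a genome build not given in the sources used here.

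Over the 464 rows tested with edgeR, 0 had an adjusted p under 0.05 and 60 had an unadjusted p under 0.05. Of the latter, 27 were higher in NPPC exosomes, all with rat names, and 33 were lower, of which 26 carried names of other species and 7 rat names. The split became 11 higher and 56 lower with total count scaling, 17 and 38 with upper-quartile factors, and 17 and 64 after a GC correction added after the data were seen. With a library left out, the number at an unadjusted p under 0.05 ran from 39 to 101. In 68 rows, 14.7% of those tested, the groups did not overlap, where chance gives 2.86% for a single row. Rows of a library vary together and some hold the same sequence. Other splits were not counted for this share, so it does not exclude chance. The DESeq2 Wald test called 11 rows, some of which held identical values, with 79 at an unadjusted p under 0.05. limma-voom called 1, miR-146a-5p, with 78. Without NPC replicate 1 edgeR called 1 row, miR-146a-5p, with a log2 fold change of 3.15 and an adjusted p of 0.00127. Over 24 alternative settings its log2 fold change lay between 2.84 and 3.69, and it passed in 15. Its adjusted p ranged from 1.42e-10 with DESeq2 to 0.263 without NPC replicate 2, where the log2 fold change was 3.55.

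**Figure D1:**
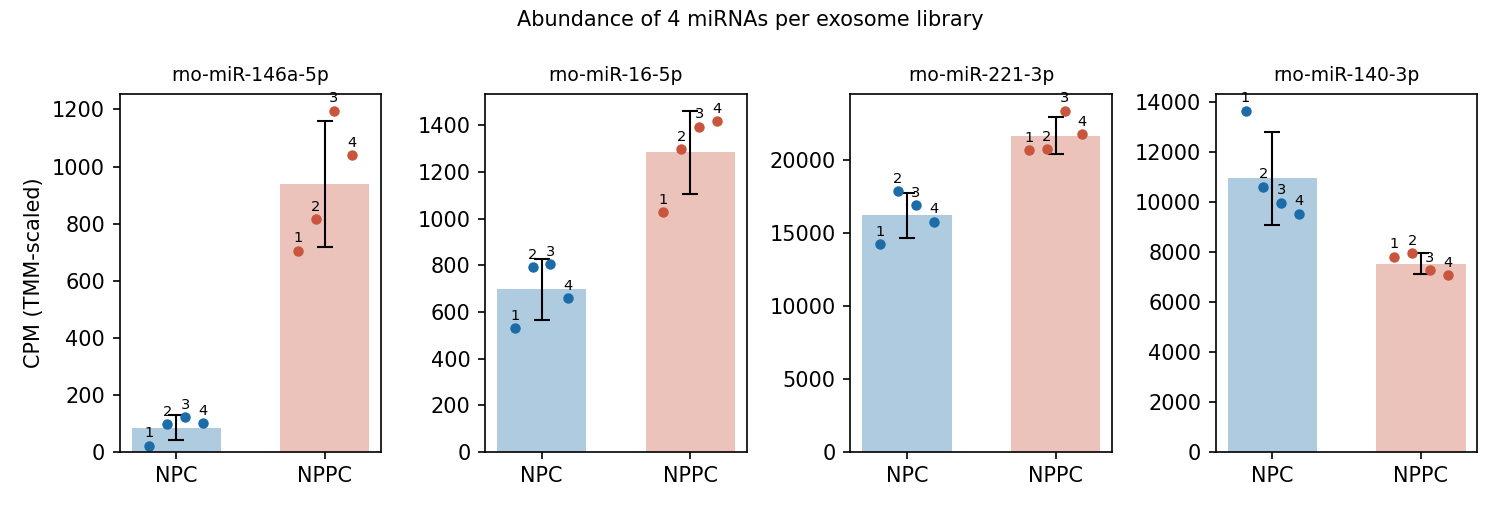
Abundance of miR-146a-5p, miR-16-5p, miR-221-3p and miR-140-3p in CPM with TMM scaling on the vertical axis, in the 4 NPC and the 4 NPPC exosome libraries. Bars are group means, error bars are SD and points are libraries numbered by replicate; miR-146a-5p averages 85.3 CPM in NPC and 939 CPM in NPPC exosomes.

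Within the lists, 6 miRNAs passed edgeR's test when adjusted over the list alone, and 0 of them passed over all rows. miR-146a-5p rose within the leukocyte list and within that of hypoxia and inflammation responsive miRNAs, which both hold it, with an adjusted p of 0.000743 over each. miR-16-5p, which represses cell cycle genes, rose by 0.88 ± 0.20 (SE) on the log2 scale, from 697 ± 129 CPM (SD, n = 4) to 1284 ± 179 CPM (SD, n = 4), with an adjusted p of 0.01001 over its family. miR-181d-5p rose by 0.80 ± 0.21 (SE) with an adjusted p of 0.0213 over the miR-181 family, and turned to -0.21 with the GC correction. miR-34a-5p, a target of p53, rose by 0.77 ± 0.24 (SE) with an adjusted p of 0.0480 over the miR-34 family. miR-221-3p, which represses the cell cycle inhibitor Cdkn1b, rose from 16206 ± 1557 CPM (SD, n = 4) to 21667 ± 1259 CPM (SD, n = 4), a log2 fold change of 0.42, with an adjusted p of 0.0198 over its cluster. With total count scaling its log2 fold change was 0.057 (adjusted p over all rows = 0.871), and those of miR-16-5p, miR-181d-5p and miR-34a-5p were 0.55, 0.45 and 0.43. miR-140-3p, from the cartilage miRNA gene inside Wwp2, fell from 10950.4 ± 1862 CPM (SD, n = 4) to 7534 ± 423 CPM (SD, n = 4), with an adjusted p of 0.0344 over the cartilage list. Its log2 fold change was -0.54, and -0.99 with total count scaling. The other arm of that hairpin, miR-140-5p, had 0.35 ± 0.40 (SE) and did not pass (adjusted p over the list = 0.815). In the deposited table the hairpins lie on chromosome 2, 165606069 to 165606166 (miR-16-5p), chromosome X, 3684480 to 3684588 (miR-221-3p) and chromosome 19, 39608948 to 39609059 (miR-140-3p).

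By camera with a preset correlation of 0.01, 4 of 20 lists passed, all higher in NPPC exosomes. With an estimated correlation 0 passed, at an adjusted p of 0.599 for let-7 and 0.571 for each of the other 3. The let-7 family, which restrains growth genes in differentiated cells, was positive in 9 of 9 members, with a median log2 fold change of 0.72 and an adjusted p of 0.0381. let-7b-5p and let-7i-5p, its members with the highest counts per row, had 0.46 and 0.72. Reads of let-7c-5p, whose sequence took 3.38% of counts on average, were divided among rows. NPC replicate 1 held 3150.0 CPM of let-7i-5p and the other NPC libraries 10249 to 12861 CPM. The miR-17~92 cluster and its paralogs, which promote proliferation, were positive in 7 of 9 members, with a median of 0.75 and an adjusted p of 0.0495. Its most abundant rows lay the other way without passing, miR-25-3p at -0.047 and miR-92a-3p at -0.30. The imprinted Dlk1-Dio3 cluster was positive in 29 of 35 members, with a median of 0.43 and an adjusted p of 0.00749. Of its most abundant rows miR-127-3p had -0.18 and miR-434-3p 0.19, which turned to -0.088 with total count scaling. miRNAs with published targets among genes of ferroptosis, the iron-dependent cell death named in the series title, were positive in 16 of 17 members, with a median of 0.53 and an adjusted p of 0.0381. miR-26a-5p had 0.53, with 2944 CPM in NPC replicate 1 and 16603 to 19456 CPM in the other NPC libraries. miR-23a-3p had 0.27, which turned to -0.0041 with total count scaling.

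Without NPC replicate 1 the log2 fold changes of let-7i-5p, miR-92a-3p, miR-127-3p, miR-434-3p, miR-26a-5p and miR-23a-3p were 0.44, -0.13, -0.0045, 0.010, 0.20 and 0.080. In each of these 4 lists 0 members passed by edgeR, adjusted over the list alone or over all rows, and 0 let-7, 3 miR-17~92, 4 Dlk1-Dio3 and 3 ferroptosis members had an unadjusted p under 0.05. The miR-17~92 and ferroptosis lists shared members, so they are not separate results. Among the shared members miR-17-5p and miR-93-5p had such a p and are counted in both lists. Without NPC replicate 1 the let-7 family had a median of 0.41 and an adjusted p of 0.0589. The other 3 passed with lower medians, 0.54 for miR-17~92, 0.22 for Dlk1-Dio3 and 0.38 for ferroptosis. Without NPC replicate 2 or NPPC replicate 4 the Dlk1-Dio3 cluster alone passed. Among rat names alone 0 lists passed, with medians of 0.55 for let-7, 0.53 for miR-17~92 and 0.23 for Dlk1-Dio3 (adjusted p = 0.246 each) and 0.34 for ferroptosis (adjusted p = 0.368). With libraries thinned to the smallest total 0 lists passed either, with medians of 0.66 (adjusted p = 0.0809) for let-7, 0.66 (adjusted p = 0.117) for miR-17~92, 0.27 (adjusted p = 0.0994) for Dlk1-Dio3 and 0.41 (adjusted p = 0.0809) for ferroptosis. The ferroptosis list did not pass with total count scaling (adjusted p = 0.0600), nor did let-7 and miR-17~92 with the GC correction (medians 0.084 and 0.40, adjusted p = 0.406 and 0.0592). With that correction Dlk1-Dio3 and ferroptosis passed at medians of 0.049 and 0.10, against 0.43 and 0.53 without it.

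**Figure D2:**
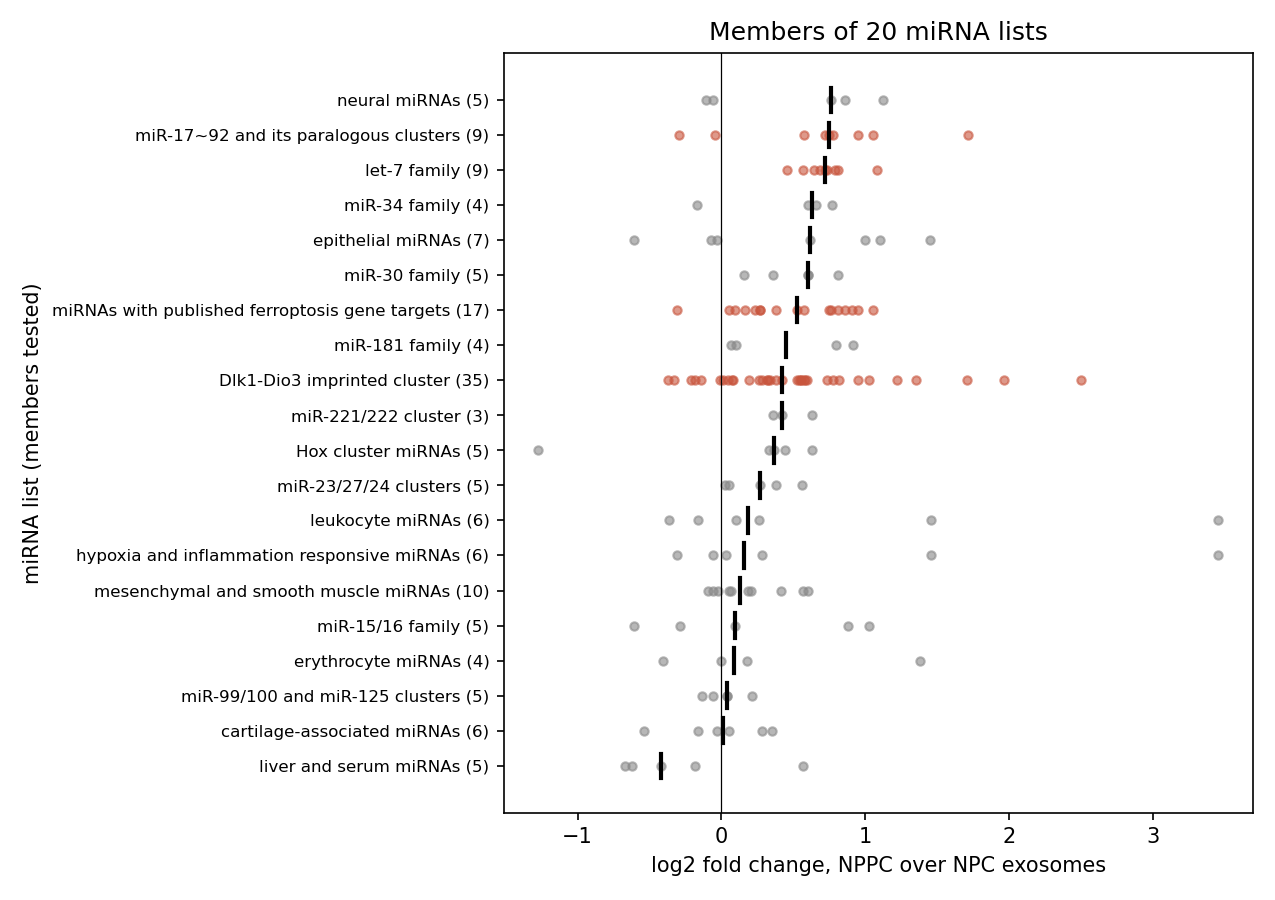
Log2 fold change of NPPC over NPC exosomes on the horizontal axis for the tested members (points) of 20 miRNA lists, with each median as a black bar. Lists in red had an adjusted p under 0.05 by camera with the preset correlation, and none did with an estimated correlation; the let-7 family has a median of 0.72.

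The other 16 lists did not pass camera with the preset correlation. The miR-30 family had a median log2 fold change of 0.60 (adjusted p = 0.139), with miR-30d-5p at 0.15, which turned to -0.24 with total count scaling, and miR-30a-5p at 0.36. Its median without NPC replicate 1 was 0.31, and it passed without a filter (adjusted p = 0.0329). The miR-181 family had 0.45 (adjusted p = 0.151), with miR-181a-5p at 0.10 and miR-181b-5p at 0.066, which turned to -0.31 and -0.31 with total count scaling. The cluster of miR-221 and miR-222 had 0.42 (adjusted p = 0.177), with miR-222-3p at 0.36, which turned to -0.12 with that scaling. The clusters of miR-23, miR-27 and miR-24 had 0.27 (adjusted p = 0.310). The miR-34 family had 0.63 (adjusted p = 0.405), with miR-34c-5p at -0.17. The family of miR-15 and miR-16 had 0.092 (adjusted p = 0.604), with miR-15b-5p at 1.03, and its median was -0.17 with total count scaling. The Hox cluster miRNAs had 0.37 (adjusted p = 0.604), with miR-10a-5p at 0.33 and miR-10b-5p at 0.44. Without NPC replicate 1 these were 0.11, 0.018 and 0.14. The mesenchymal and smooth muscle list had 0.13 (adjusted p = 0.418), and its median was -0.35 with total count scaling. The cartilage list had a median of 0.013 (adjusted p = 0.853), a mean of -0.0069 and a negative test direction, with miR-148a-3p at -0.16. The clusters of miR-99, miR-100 and miR-125 had a median of 0.037 (adjusted p = 0.970), a mean of 0.019 and a negative test direction. Of these miR-125b-5p had 0.21, which turned to -0.17 with total count scaling, and miR-99a-5p had -0.057. The hypoxia and inflammation list had 0.16 (adjusted p = 0.405), with miR-210-3p, which low oxygen induces, at -0.31.

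Among markers of other cell types, the leukocyte list had a median log2 fold change of 0.18 (adjusted p = 0.100), with miR-155-5p at 1.46. It passed without a filter, with the GC correction, with total count scaling and with upper-quartile factors (adjusted p = 0.0135, 0.0179, 0.0348 and 0.0391), with medians of 0.15, 0.037, -0.088 and 0.015. With a library left out its median ran from 0.087 without NPPC replicate 1 to 0.70 without NPC replicate 2, and it did not pass. The erythrocyte list had 0.088 (adjusted p = 0.853), with miR-451-5p at 1.38 and miR-486 at -0.41. Without NPPC replicate 2 these were -0.052, 0.14 and -1.49. The neural list had 0.76 (adjusted p = 0.405), with miR-7a-5p at 0.86 and miR-128-3p at -0.11, which were 0.38, 0.47 and -0.18 without NPC replicate 1. The epithelial list had 0.62 (adjusted p = 0.405), with miR-182 at 1.00 and miR-203a-3p at 1.45, and a median of 0.17 without NPPC replicate 2. Without that library miR-203a-3p was 0.91, and miR-182 was 0.59 without NPC replicate 1. The liver and serum list had -0.42 (adjusted p = 0.663), with miR-423-5p at -0.42 and miR-192-5p at -0.67, which were 0.11, -0.45 and 0.11 without NPC replicate 3. Lists with under 3 tested members were not tested by camera. These were the miR-29 family (miR-29a-3p at 0.68, miR-29b-3p at 0.97), the endothelial list (miR-126a-3p at -0.049, miR-126a-5p at 0.41) and the muscle list (miR-499-5p at 0.77). Without NPC replicate 1 these 5 were 0.45, 0.57, -0.27, 0.14 and 0.41, and with the GC correction miR-29a-3p, miR-126a-5p and miR-499-5p turned to -0.14, -0.65 and -0.28. The muscle list also held miR-1-3p at 0.10, which turned to -0.045 with total count scaling and -0.30 without NPC replicate 1. Of the embryonic stem cell clusters 0 of 16 members were abundant enough to be tested.

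NPC replicate 1 stood apart from the other libraries. Its TMM factor was 1.82, where the others lay between 0.839 and 1.01, and on the first principal component (59.5% of the variance) it lay at -42.3, with the others between -10.7 and 12.8. Over 173 rat rows, which are not independent replicates, the Spearman correlation of GC percent with a row's deviation from its mean over the libraries was 0.927 in NPC replicate 1. It was -0.038, -0.59 and -0.21 in the other NPC libraries and -0.49, -0.75, -0.73 and -0.76 in the NPPC libraries. The mean includes NPC replicate 1, whose trend pushes the other libraries to the opposite sign, so their sign does not show a trend of their own. That push is shared by these libraries. It does not by itself account for the differences among them, from -0.038 in NPC replicate 2 to -0.76 in NPPC replicate 4.

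**Figure D3:**
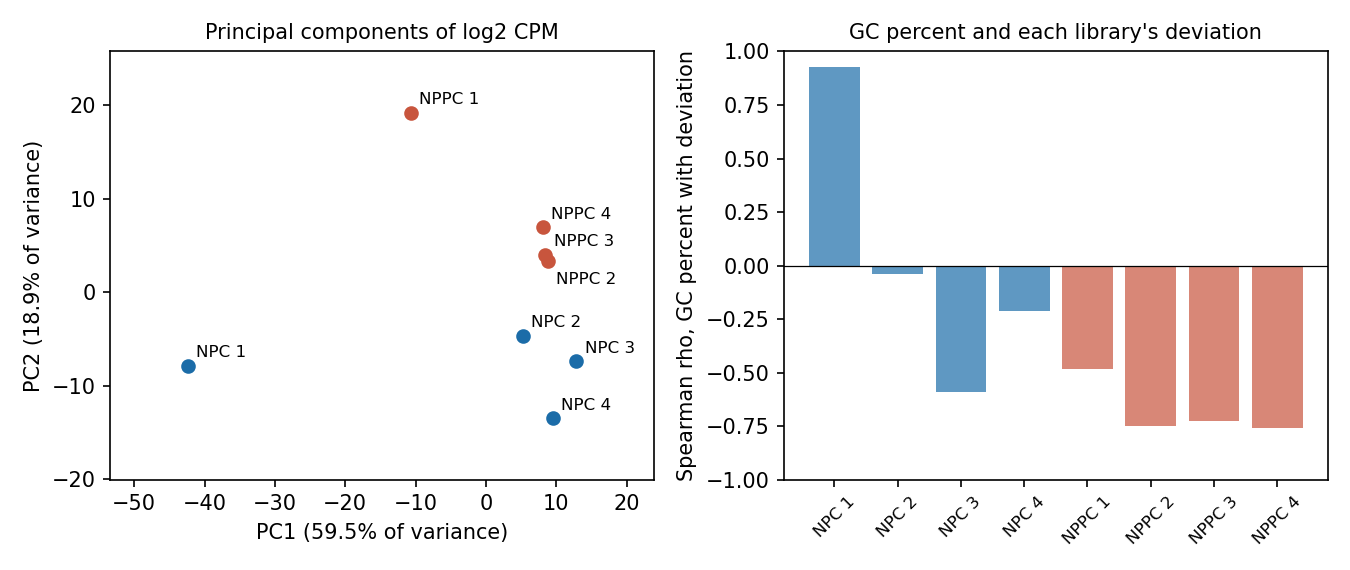
Left, the first and second principal components of log2 CPM, with points as libraries labelled by group and replicate. Right, as 1 bar per library, the Spearman correlation across 173 rat miRNA rows of GC percent with the library's deviation from the mean. It was 0.927 in NPC replicate 1 and below 0 in the other 7 libraries, where the mean holds NPC replicate 1.

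Rat miRBase miRNAs held 95.5% ± 1.38 (SD, n = 4) of NPC and 97.8% ± 0.267 (SD, n = 4) of NPPC counts, a difference of 2.32 percentage points. Rows named after other species held 3.43% ± 1.00 (SD, n = 4) and 1.79% ± 0.204 (SD, n = 4), and predicted candidates held 1.12% ± 0.382 (SD, n = 4) and 0.445% ± 0.114 (SD, n = 4). In each of the 3 classes the groups did not overlap, with a two-sided exact permutation p of 0.0286 and a Benjamini-Hochberg adjusted p of 0.0286 over 4 tests. With an NPPC library left out the exact permutation p for the rat share was 0.0857. After thinning each library to the smallest total, 709.5 ± 132 (SD, n = 4) rows were detected in NPC and 693 ± 70.03 (SD, n = 4) in NPPC exosomes, with an exact permutation p of 0.886. Few deposited counts lay under 5, while thinning creates such counts in the deeper libraries. The comparison at a minimum of 1 count is therefore distorted by depth. At a minimum of 5 counts 519.7 ± 51.8 (SD, n = 4) and 443 ± 14.8 (SD, n = 4) rows were detected, with an exact permutation p of 0.0286. After summing rows per sequence, 110 of 5153 deposited values above 0 were under 5 and none of the deposited values was 1, so a listed 0 need not mean that no read was present.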

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

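The tests below were chosen after the results they bear on had been seen, except that of hairpin arms, which was fixed before its result. Fits with a library left out or an estimated correlation had been fixed beforehand, but not their use to weigh explanations.

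Of 104 groups of 4 libraries examined, 11 held a library far from the other 3, where chance gives about 1 in 20. In NPC replicate 1 miR-25-3p stood at 4992 CPM (others 4275 to 4344), miR-29b-3p at 0 CPM (others 24.1 to 27.5) and miR-499-5p at 13.4 CPM (others 127 to 146.16). In NPPC replicate 1 miR-27b-3p stood at 54593 CPM (others 62007 to 62634), let-7b-5p at 12475 CPM (others 19602 to 20218) and miR-423-5p at 2919.9 CPM (others 1787 to 1894). The correlation of GC percent with the deviation was -0.485 there, and -0.758 to -0.727 in the other NPPC libraries. NPPC replicate 2 held miR-451-5p, a red cell miRNA, at 877 CPM (others 100.2 to 219.7) and miR-499-5p at 202 CPM (others 172 to 174). NPC replicate 3 held miR-192-5p at 642 CPM (others 145.98 to 191), and NPC replicate 4 held miR-30d-5p at 3552 CPM (others 3996 to 4049.9).

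NPC replicate 1 stood apart. Low depth is argued against, since over 79 rows of at least 1000 CPM, with libraries thinned alike, the SD of its deviations was 2.14 against at most 0.346 in the other NPC libraries, a ratio of 6.17. RNA of another listed cell type cannot be told apart by the 7 lists, whose highest median deviation was -0.68. The deviations were not corrected for GC percent, with which those of this library correlated at 0.927, so an added cell type need not have raised a median. A recovery that falls with AU content is a candidate explanation, since over 68 hairpins with both arms tested the difference in deviation followed that in GC percent with a Spearman rho of 0.523, just above the bound of 0.5 (permutation p = 1e-05, the smallest that the permutations can give). That p measures the spread over hairpins within this 1 library. The rho is not separate from the correlation of 0.927 over rows. The same rho was -0.175, -0.519 and -0.401 in the other NPC libraries, whose reference holds NPC replicate 1, and 0.277, -0.268, -0.0139 and -0.112 in NPPC replicates 1 to 4, and no biological explanation was tested.

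miR-146a-5p was higher in NPPC exosomes. NPC replicate 1 alone is argued against by a log2 fold change of 3.15 ± 0.25 (SE) without it, and reads moved from miR-146b-5p by a log2 ratio of 1.64 between the group means of both summed. Leukocyte RNA that raised all its miRNAs alike is argued against by the other 5 leukocyte miRNAs, whose median was 0.10 with an SD of 0.71. They ran from -0.36 ± 0.99 (SE) for miR-142-5p to 1.46 ± 0.61 (SE) for miR-155-5p, so a smaller rise is not excluded. Without NPC replicate 2 the median of the whole leukocyte list was 0.70. With libraries thinned to the same total the log2 fold change was 3.49 with an adjusted p of 0.0317, while a difference between the cell types stays open as untested. The splits decide nothing for edgeR's count of 0 rows, which 35 of 35 reach (highest other 0). DESeq2 called 11 rows and limma-voom 1. For the 60 rows at an unadjusted p under 0.05, 1 of 35 splits gave as many, with a highest other of 44. That is the smallest share 35 splits can give and was not adjusted for the other counts compared, so it does not exclude chance. The split with 44 rows, unlike the real one, put both libraries numbered 1 in one group.

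Camera called 4 lists as higher in NPPC exosomes with the preset correlation and 0 with an estimated one (adjusted p = 0.571 to 0.599). Without NPC replicate 1 the Dlk1-Dio3, miR-17~92 and ferroptosis lists passed with the preset correlation. Their median differences in log2 CPM (0.30, 0.54 and 0.41) lay above those of the other 34 splits. Their positive medians therefore did not rest on that library alone. These 3 lists had been chosen for passing in the real split of the same libraries, which favours that split. The estimated correlation was not applied without that library, so whether the 3 lists differ without it is not decided. For let-7 NPC replicate 1 alone cannot be told apart. Without that library the family did not pass camera (adjusted p = 0.0589), and 6 of 35 splits reached its difference (0.39). With neither library numbered 1 edgeR called 6 of 9 let-7 members (median 0.55, camera adjusted p = 0.00331), but the 10 splits there are too few to decide. A GC trend over all libraries cannot be told apart, since 0 of the 4 lists passed in both GC-corrected comparisons. Without NPC replicate 1 the correction took their medians from 0.41 to 0.061 (let-7), 0.54 to 0.26 (miR-17~92), 0.22 to 0.0096 (Dlk1-Dio3) and 0.38 to 0.13 (ferroptosis). Less the median of all rows, which the correction lowered too, they went from 0.40 to 0.21, 0.53 to 0.41, 0.22 to 0.16 and 0.37 to 0.28 in this order. Low values of rows outside the rat miRNAs in the comparison set cannot be told apart either, since 0 of the 4 lists passed among rat names alone. With all libraries the medians less that of all rows fell there from 0.67 to 0.48, 0.71 to 0.46, 0.38 to 0.17 and 0.48 to 0.28 in this order. Nor can a difference in depth between the groups, since 0 of the 4 passed with thinned libraries, where counts under 5 were also set to 0. With thinning the same medians went from 0.67 to 0.69, 0.71 to 0.69, 0.38 to 0.31 and 0.48 to 0.44. A difference between the cell types stays open as untested. With the preset correlation the real split gave 4 lists, the highest other 2 and 1 of 35 splits as many, the smallest share 35 splits can give. Without NPC replicate 1, 5 of 35 gave as many as the real 3 and the highest other 4, so chance is not excluded.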

How the results depend on the processing

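The authors' scaling, sums per sequence, the GC corrections, neither library numbered 1 and thinning were added after the data were seen, as were for lists upper-quartile factors, both filters, sums per mature name and rat names only. edgeR called 0 rows (60 at an unadjusted p under 0.05), and also 0 with the filter of 10 CPM, which kept more rows, and with the replicate block. It called 1, miR-146a-5p, with DESeq2 size factors, total count scaling, upper-quartile factors, no filter, sums per mature name, rat names only, the authors' scaling, sums per sequence and thinning, as did limma-voom. With a library left out it called 0 to 1, the 1 without NPC replicate 1. The DESeq2 Wald test called 11, the GC correction 3, the GC correction without NPC replicate 1 5 and neither library numbered 1 53. For the 3 rows of the GC correction 1 of 35 splits gave as many (highest other 0), the smallest share 35 splits can give. Without NPC replicate 1, 3 of 35 splits called as many as the real 1 and the highest other 11, so chance cannot be excluded, and the latter points to a structure of the libraries, whose nature was not tested. At an unadjusted p under 0.05 the real split there gave 101 rows and the highest other 83 (1 of 35 splits as many). For the 3 lists 5 of 35 splits gave as many (highest other 4), so chance is not excluded. For neither library numbered 1 the 10 splits are too few for a share under 0.05 (1 as large, real 53, highest other 0; for lists 1, 4 and 3). Camera called 4 lists, and 4 with DESeq2 size factors, the replicate block, the filter of 10 CPM, the authors' scaling and neither library numbered 1. It called 5 with upper-quartile factors, which added the leukocyte list (adjusted p = 0.0391), and 6 without a filter, which added the leukocyte list (0.0135) and the miR-30 family (0.0329). With total count scaling it also called 4, with the leukocyte list (median -0.088, test direction positive) in place of the ferroptosis list. The 3 with the GC correction were the Dlk1-Dio3, ferroptosis and leukocyte lists, with medians of 0.049, 0.10 and 0.037 (1 of 35 splits as many, highest other 2). The shares of 1 of 35 splits were not adjusted for the number of counts compared. It called 3 with sums per sequence, without miR-17~92, 2 with sums per mature name and 0 with the estimated correlation, rat names only, thinning, and the GC correction without NPC replicate 1. With a library left out it called 1 to 4, with 1 without NPC replicate 2 or NPPC replicate 4 and 2 without NPPC replicate 3. The replicate numbers were not taken as pairs, which would need every same-numbered pair to correlate above 0.1, as their deviations correlated at 0.57, 0.15, 0.22 and 0.041. Of the same-numbered pairs only that numbered 1 was mutually best, and NPC replicate 3 with NPPC replicate 4 and NPC replicate 4 with NPPC replicate 3 were mutually best too. The median over rows of the shift in log2 fold change was -0.32 with total count scaling, -0.19 with upper-quartile factors and -0.12 without NPC replicate 1. It was -0.16 with the GC correction and -0.26 with it and no NPC replicate 1.

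The number of rows detected differed by -16.4 between NPPC and NPC, by 19.5 unthinned, by -76.8 at 5 counts and by -67.3 to 40.2 with a library left out. The share of the 10 most abundant rows differed by 0.450 to 4.36 percentage points with a library left out, the lowest without NPC replicate 1 and the highest without NPC replicate 3. The rat share differed by 1.89 to 2.73 points, with an exact permutation p of 0.0857 without each NPPC library in turn. Of 47 miRNAs named, 22 kept their sign in all settings and 25 did not, and of 20 lists 12 kept camera's test direction, which is set against all rows, and 8 the sign of their median. The test direction held while the median turned to -0.17 for the family of miR-15 and miR-16, -0.13 for the hypoxia list, -0.33 for the cartilage list, -0.39 for that of miR-99, miR-100 and miR-125 and -0.011 for that of miR-23, miR-27 and miR-24 with total count scaling. It also held for the family of miR-15 and miR-16 at -0.36 and the miR-30 family at -0.0063 with the GC correction. List values below are medians where the test direction turned, and those of the cartilage list, of miR-99, miR-100 and miR-125 without a filter and of miR-23, miR-27 and miR-24 kept their sign. The cause of these changes was not tested. Log2 values with total count scaling were miR-199a-3p -0.0085, miR-27b-3p -0.27, miR-434-3p -0.088, miR-30d-5p -0.24, miR-181a-5p -0.31, miR-181b-5p -0.31 and miR-222-3p -0.12. Log2 values with total count scaling were miR-23a-3p -0.0041, miR-125b-5p -0.17, miR-1-3p -0.045 and mesenchymal list -0.35. Log2 values with upper-quartile factors were miR-27b-3p -0.15, miR-30d-5p -0.11, miR-181a-5p -0.18, miR-181b-5p -0.18 and miR-125b-5p -0.040. Log2 values without a filter were miR-199a-5p 0.012, cartilage list 0.045 and list of miR-99, miR-100 and miR-125 0.063. The log2 value of miR-126a-3p with limma-voom was 0.055. The log2 value of miR-126a-3p with the replicate block was 0.065. Log2 values with sums per mature name were miR-27b-3p -0.012 and miR-181b-5p -0.0080. Log2 values with rat names only were miR-27b-3p -0.16, miR-434-3p -0.014, miR-30d-5p -0.092, miR-181a-5p -0.15, miR-181b-5p -0.17, miR-125b-5p -0.030 and miR-1-3p -0.061. Log2 values with rat names only were mesenchymal list -0.18, list of miR-23, miR-27 and miR-24 0.067 and erythrocyte list -0.073. Log2 values with the GC correction were miR-199a-3p -0.34, miR-27b-3p -0.22, miR-434-3p -0.21, miR-29a-3p -0.14, miR-30d-5p -0.0063, miR-30a-5p -0.022 and miR-181a-5p -0.21. Log2 values with the GC correction were miR-181b-5p -0.40, miR-10a-5p -0.26, miR-10b-5p -0.18, miR-23a-3p -0.12, miR-26a-5p -0.031, miR-126a-5p -0.65 and miR-499-5p -0.28. Log2 values with the GC correction were miR-1-3p -0.76, miR-181d-5p -0.21, mesenchymal list -0.22, miR-181 list -0.21, Hox list -0.18 and erythrocyte list -0.36. Log2 values with the GC correction and no NPC replicate 1 were miR-21-5p -0.058, miR-199a-3p -0.30, miR-27b-3p -0.22, miR-434-3p -0.22, miR-181a-5p -0.0048, miR-181b-5p -0.14 and miR-10a-5p -0.27. Log2 values with the GC correction and no NPC replicate 1 were miR-10b-5p -0.14, miR-23a-3p -0.14, miR-26a-5p -0.099, miR-126a-5p -0.21, miR-1-3p -0.75, Hox list -0.17 and erythrocyte list -0.39. Log2 values with neither library numbered 1 were miR-199a-5p 0.015, miR-25-3p 0.039, miR-1-3p -0.32 and erythrocyte list -0.27. Log2 values with thinned libraries were miR-27b-3p -0.015, miR-181b-5p -0.051 and erythrocyte list -0.083. With a library left out the values ran from -0.043 to 0.41 for miR-199a-3p, -0.047 to 0.15 for miR-27b-3p, -0.095 to 0.019 for miR-25-3p, -0.30 to 0.37 for miR-1-3p, -0.064 to 0.11 for list of miR-99, miR-100 and miR-125. With a library left out the values ran from -0.23 to 0.39 for erythrocyte list, -0.26 to 0.010 for miR-143-3p, -0.13 to 0.078 for miR-99a-5p, -0.27 to 0.17 for miR-126a-3p, -0.86 to 0.11 for miR-192-5p. With a library left out the values ran from -0.52 to 0.11 for liver and serum list, -0.072 to 0.0040 for miR-199a-5p. Depth limits low rows, as the shallowest library held 329011 counts.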

Other observations

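The comparison with neither library numbered 1, 3 libraries against 3, was chosen after the data were seen. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment it called 53 rows, 31 higher and 22 lower in NPPC exosomes. All those higher carried rat names, with the smallest p in miR-146a-5p at a log2 fold change of 3.28. Also higher were let-7b-5p at 0.50, let-7i-5p at 0.55, miR-16-5p at 0.89, miR-15b-5p at 0.89, miR-29a-3p at 0.51 and miR-155-5p, an miRNA of activated immune cells, at 1.22. Of those lower 11 were predicted candidates, 8 carried names of other species, among them mir-5119 and mir-6236, and 3 rat names, among them miR-140-3p at -0.41 and miR-148a-3p at -0.40. Some called rows held identical values, such as those of let-7c-5p, whose reads were divided among rows, and of miR-17-5p and mir-6236. The number of rows called is therefore higher than that of separate results. The deviations of the libraries numbered 1 from their group means correlated at 0.57, and the labels give no batch, so whether they were prepared apart from the others is not known.

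Families of rows named after other species were chosen after their values were seen, so no test is given. Rows named after mir-6236 held 2888 ± 1069.7 (SD, n = 4) CPM of the library total in NPC and 1042 ± 426 (SD, n = 4) CPM in NPPC exosomes. Rows named after mir-5119 held 27.4 CPM in NPC replicate 1 and 59.2 CPM in NPPC replicate 1, and from 2260.4 to 14514 CPM in the other 6 libraries.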
